A study of Mus musculus with 6 samples.

How the data were processed

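Gene expression was measured on 6 microarrays of mouse long-term haematopoietic stem cells (LT-HSC), the population of bone marrow that can rebuild all blood lineages after a transplant. Per the labels, the cells were sorted 4 months after bone marrow transplantation, and each array holds RNA from a pool of animals: 3 control pools and 3 pools expressing NPMc+, a mutant nucleophosmin found in the cytoplasm. About 5 ng of total RNA was amplified and labelled with biotin, per the labels' protocols. The groups and the replicate numbers 1 to 3 were taken from the sample titles.

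The table the authors deposited holds log2 expression values of 41345 probe sets for the 6 arrays. The submitters' processing notes name RMA, a method that corrects background, normalizes arrays to each other and summarises the probes of a probe set; its version, and any later step, are not given in the sources used here. Array medians lay between 3.90 and 3.99 log2 units. For arrays, the number of samples limits the precision, and no background measurement was used here.

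Same-numbered arrays of the groups were found to be tied to each other. In 100% of the 41345 probe sets the mean of control and NPMc+ was the same for replicates 1, 2 and 3 within 0.001 log2 units, with a largest range of 6.5e-05. Under any of the 5 other ways to pair the arrays, at most 0.343% of probe sets met that tolerance. The deviations of same-numbered arrays from their group means correlated at -1 across probe sets in each of the 3 pairs. An effect of the replicate number was therefore already taken out of the deposited values, and only the differences within the 3 pairs carry an independent spread.

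The design fixed before the data were examined was a limma fit without a block, with the replicate number as a block among the alternatives listed with it. That fit counts 4 residual degrees of freedom where the values hold 2. On 20 simulated sets of 16635 genes treated in the same way, with 200 genes changed in each, 19.7% of unchanged genes had p under 0.05 without the block and 4.99% with it. The values reported here therefore come from the blocked fit, with 2 residual degrees of freedom and 4.537 prior degrees of freedom. This choice departs from the fixed design and was made after the fit without the block had been run; the results without the block stand beside the counts they change. In the simulation the blocked fit recovered 4.95% of genes changed 2-fold and 86% of genes changed 4-fold, with a slope of fitted on true log2 change of 0.997. A B cell list lowered 2-fold was called in 10 of 10 simulations that held it. The genes were simulated as independent, so this does not show how camera behaves when genes of a list vary together. In the real data the estimated correlation within a list reached 0.551, for erythroid markers.

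Gene names came from a platform annotation listing. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Symbols were looked up by gene identifier for 23328 probe sets in a RefSeq table of the GRCm38.p6 assembly, used for names only, and 0 changed. The 23521 probe sets stood for 22180 genes, of which 1082 had more than 1 probe set and were represented by the probe set with the highest mean over the 6 arrays. Genes with a mean below the 25th percentile were left out, so that 16635 were tested, with a lowest mean of 3.01 log2 units. No gene was named from a probe set with several symbols; genes that have no probe set of their own, such as Trp53, were not analysed here, and genome positions are not given because the labels name no build.

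Differences are NPMc+ minus control on the log2 scale. They were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (version 1.17.8), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A looser count took genes at an unadjusted p under 0.01 that differed at least 1.5-fold. Gene lists were tested as groups with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists; camera asks whether a list moves relative to the other genes. The same test with a correlation estimated for each list, and limma's fry, which asks whether a list's genes move on balance in 1 direction, were run as alternatives. P-values of list members were also adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

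The following choices were made before the data were examined: the groups, the thresholds, the 22 gene lists, the alternatives and the rule for named genes. By that rule, the text names the 12 genes with the largest rise and the 12 with the largest fall past the adjusted threshold whose groups do not overlap. A direction with fewer is filled, as happened for both, with the genes of smallest unadjusted p that differ at least 1.5-fold without overlap of the groups. Predicted genes, Riken clones, small RNAs and olfactory and vomeronasal receptor genes were left out of this part; 2 such names in each direction had a p as small as the genes listed. The rule adds 13 genes of stem cell and cell cycle biology that had a probe set of their own, and the 4 members of each list with the smallest p. The last part was followed only in part, and not all of these list members are named below. Other members are named as examples of their list and were chosen after their values were seen. The lists cover HSC quiescence regulators, LT-HSC identity genes, multipotent and lymphoid progenitor genes, G1/S genes, G2/M genes, genes of entry from G0 into G1, the Hoxa and Hoxb clusters with cofactors, p53 targets, TGF-beta and BMP signalling, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, glycolysis, interferon response, immediate early and heat shock genes, niche adhesion and homing genes, and markers of erythroid, megakaryocyte, neutrophil and monocyte, T and NK, B and stromal or endothelial cells.

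The alternatives were the fit without the block, quantile normalization, centring each array on its median, no filter on dim genes, a filter at the 50th percentile, the mean of all probe sets of a gene, an intensity trend with robust hyperparameters, array weights, leaving out arrays, other thresholds, and all probe sets with or without a symbol. Under the block an array without its partner carries no information, so leaving out either array of a pair leaves out the pair. Comparisons of groups of genes in the closing section used two-sided permutation tests over genes with 100000 resamples, and a one-sample t test of the 3 pair values where a comparison had 3. The t tests were added after the permutation results were seen, because genes that vary together are not independent replicates.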

Results

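The data comprised 6 arrays of LT-HSC RNA, 3 from control pools and 3 from NPMc+ pools, in 3 same-numbered pairs. Each pool was a separate sample of several animals per the labels. The p-values of single genes rest on the spread of the 3 differences within pairs, combined with a prior drawn from all genes. Camera with a preset correlation compares a list's genes with the other genes and treats genes as nearly independent. Its p-values therefore do not measure the spread between pools. The comparison asked how sorted stem cell samples expressing the mutant nucleophosmin differ in gene expression from control samples in marrow rebuilt by a transplant. The series title places it in the context of stem cell dormancy and self-renewal in leukaemia. Some genes of other or cycling cells had high signals in both groups. Mmp8, a neutrophil marker, had means of 10.82 log2 units in control and 9.02 in NPMc+, and Mki67 10.09 and 9.83. Of LT-HSC identity genes, Procr had 5.33 and 5.41 and Angpt1 9.05 and 10.02. Levels of unlike probe sets do not measure shares of cells. Pools differed in their sex-linked transcripts. Xist, the RNA of the inactive X chromosome, differed between NPMc+ and control by -5.44 log2 units in pair 1, by -5.39 in pair 2 and by 0.48 in pair 3, and the mean of the Y chromosome genes Uty, Kdm5d and Eif2s3y differed by 4.55, 0.86 and -0.37.

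In limma's camera test with a preset correlation, 8 of 22 gene lists passed, 4 higher and 4 lower in the sorted NPMc+ samples. With an estimated correlation 0 of the 22 passed (adjusted p = 0.269 to 0.320 for the 8), and with limma's fry 1 passed. The test with an estimated correlation uses the 2 residual degrees of freedom as its own, so it has little power here. For B cell markers, with an estimated correlation of -0.0786, its unadjusted p was 0.0122 against 2.56e-17 in camera with the preset. Failing it therefore does not tell an unchanged list from a shift it cannot detect. The 4 higher lists were genes of the stem cell state, the Hoxa and Hoxb clusters, the megakaryocyte lineage and the immediate early response. Some genes belong to more than 1 list, so the lists are not independent of each other. The 4 lower lists were markers of B cells, erythroid cells, neutrophils and monocytes, and T and NK cells, lineages that a stem cell sort should exclude. The lists hold genes of committed precursors beside those of mature cells, among them Ebf1, Mpo and Elane. The megakaryocyte list, which rose, also holds markers of cells that a stem cell sort should exclude. The group differences were moderate in size: the LT-HSC identity list rose by a median of 0.38 log2 units and the B cell list fell by a median of 1.23 (adjusted p = 0.301 and 0.269 with an estimated correlation). The medians of all 8 lists had 1 sign in 3 of 3 pairs, as had those of 5 of the 14 other lists. Of single genes, 0 passed the adjusted threshold in the blocked limma fit, while 1492 had an unadjusted p under 0.05 where chance gives 832. The smallest adjusted p in limma was 0.0928.

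At an unadjusted p under 0.01, 388 genes stood out where chance gives 166, 226 higher and 162 lower in NPMc+. All 388 differed at least 1.5-fold, but this bound added nothing. Even with the smallest SE the blocked fit allows, a p under 0.01 requires more than a 1.5-fold difference. After quantile normalization the split was 174 higher and 189 lower. The limma fit without the block called 828 genes at an adjusted p under 0.05, 557 higher and 271 lower. All 828 moved 1 way in 3 of 3 pairs, which a call at that threshold requires in these values. With the block, 717 had an unadjusted p under 0.05. Both fits use the same 3 pair differences, so neither count is separate support for the 828 calls. Over all 16635 genes tested, 30.3% moved 1 way in the 3 pairs where chance gives 25%, and the differences of any 2 pairs correlated across genes at 0.161 to 0.175, genes not being independent replicates. With the median SE of 0.202 log2 units, a difference of 1.4-fold reached an unadjusted p of 0.05. Leaving out pair 3 gave 24 genes past the adjusted threshold in limma, 1 higher and 23 lower, and leaving out pair 2 gave 3.

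Npm1 itself, the gene of nucleophosmin, had a mean of 11.76 log2 units in control and 11.57 in NPMc+, a difference of -0.19 ± 0.18 (SE; 95% interval -0.62 to 0.24). The labels do not say where the mutant was expressed from or whether the probe set reads it, so this value does not check the group labels. The 12 genes named as higher had limma adjusted p-values of 0.163 to 0.266. P2ry14, a receptor for UDP-glucose, was 3.37-fold higher (1.75 ± 0.18 log2 units, SE). Myct1 was 2.48-fold higher and Itga2b, the CD41 integrin chain of megakaryocytes and early progenitors, 2.51-fold higher. Clnk, an adaptor of immune receptor signalling, was 2.98-fold higher, Afap1l1 2.84-fold, Pvr 2.61-fold, Zfp385a 2.53-fold and Hoxa5 2.51-fold. Itih5, Pcp4l1, Nrgn and Tspan14 were 2.45-fold, 2.42-fold, 2.27-fold and 2.19-fold higher.

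Several of the 12 genes named as lower are known from lymphocytes. Ms4a1, which encodes CD20, was 4.13-fold lower (-2.05 ± 0.18 log2 units, SE) and Ebf1, a transcription factor of B cell commitment, 4.51-fold lower (-2.17 ± 0.19), both with a limma adjusted p of 0.0928. The B cell adaptor Blnk was 3.68-fold lower and Cd79a, a chain of the B cell receptor, 2.36-fold lower. Of T and NK cell genes, Cd3d was 2.78-fold lower, Cd2 2.81-fold lower and the chemokine Xcl1 4.68-fold lower. Clec4a3, a lectin of myeloid cells, was 6.16-fold lower, and Irf4, Gpr18, Olfm4 and Orm1 were 3.0-fold, 2.67-fold, 3.52-fold and 2.45-fold lower. All 24 genes had 1 sign in 3 of 3 pairs, as the rule requires, and the limma adjusted p-values in the lower direction were 0.0928 to 0.246.

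**Figure D1:**
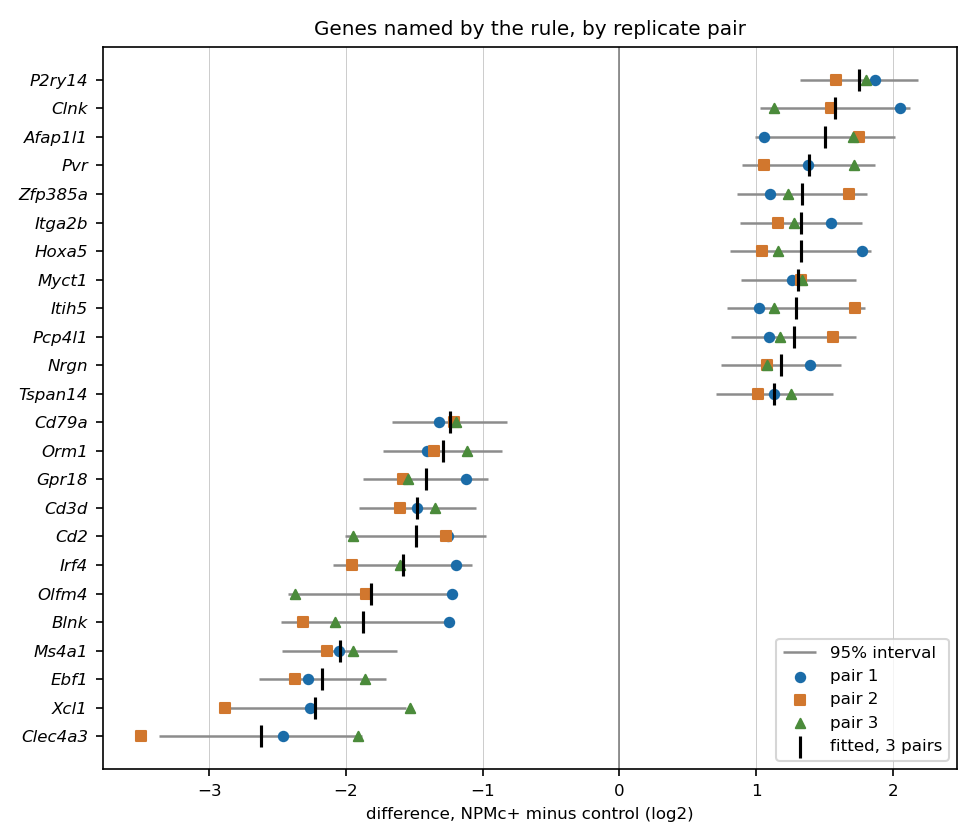
Difference between NPMc+ and control in log2 units (x axis) for the 24 genes named by the rule (y axis); symbols are the 3 replicate pairs, black ticks the fitted difference and grey lines its 95% interval. The 12 higher genes lie between 1.13 and 1.75 and the 12 lower genes between -2.62 and -1.24, and each gene has its 3 pairs on 1 side of 0.

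LT-HSC identity genes rose as a group. Of the 30 tested, 24 were positive, 10 were higher at an unadjusted p under 0.05 and 0 lower. When adjusted over the list alone 8 passed, and 0 over all genes tested. Among the 8 were Hoxa9, Hoxb5 and Meis1, which are also counted with the Hoxa and Hoxb clusters below. Mecom, a transcription factor needed for stem cell maintenance, was 2.51-fold higher (1.33 ± 0.31 log2 units, SE), Gata2 2.06-fold, Angpt1 1.96-fold, Erg 1.87-fold and Meis1 1.82-fold. Procr, a surface marker of the most primitive cells, differed by 0.08 ± 0.19. Camera gave an adjusted p of 2.16e-05 in limma, and adjusted p = 0.301 with an estimated correlation. The list's median was 0.25 log2 units without pair 3, against 0.38 with all pairs.

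The Hoxa and Hoxb clusters with their cofactors rose as a group, by a median of 0.46 log2 units. These homeobox genes are expressed in stem and progenitor cells and are often high in leukaemia with mutant nucleophosmin. Of the 19 tested, 8 were higher at an unadjusted p under 0.05 and 0 lower, and 7 passed when adjusted over the list alone against 0 over all genes. Hoxa9, Hoxb5 and Meis1 were counted among the LT-HSC identity genes too. Hoxa5 was 2.51-fold higher, Hoxa6 2.44-fold, Hoxa2 2.20-fold, Hoxb5 2.14-fold, Hoxa9 2.08-fold (1.06 ± 0.25 log2 units, SE) and Hoxa7 1.95-fold; Hoxa10 was 1.37-fold higher and Hoxb4 1.22-fold. The limma camera adjusted p was 4.13e-06, and adjusted p = 0.301 with an estimated correlation. Without pair 1 the list's median was 0.73, and without pair 2 it was 0.30.

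Megakaryocyte and platelet markers rose by a median of 0.51 log2 units (limma camera adjusted p 5.42e-04; adjusted p = 0.301 with an estimated correlation). Of 19 tested, 9 were higher and 2 lower at an unadjusted p under 0.05, and 1, Itga2b, passed when adjusted over the list alone against 0 over all genes. The glycoprotein gene Gp5 was 2.68-fold higher, the platelet chemokine genes Ppbp and Pf4 2.34-fold and 2.21-fold, and Selp 1.73-fold, while Thbs1 was 1.98-fold lower and Gp6 1.37-fold lower. Immediate early and heat shock genes, which respond within minutes to signals and to handling of cells, rose by a median of 0.32 (limma camera adjusted p 6.96e-04; adjusted p = 0.320 with an estimated correlation). Of these 25 genes, 5 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. All 5 encode transcription factors: Jun was 1.57-fold higher, Egr1 1.56-fold, Klf6 1.47-fold, Fosb 1.45-fold and Nr4a1 1.40-fold.

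B cell markers fell furthest among the lists, by a median of 1.23 log2 units, with pair medians of -1.25, -0.92 and -0.81. All 13 tested were lower in NPMc+, 9 of them at an unadjusted p under 0.05; 8 passed when adjusted over the list alone and 0 over all genes tested. Beside the genes named above, Vpreb3 was 2.91-fold lower, Pou2af1 2.63-fold and Cd22 2.35-fold. The limma camera adjusted p was 5.62e-16, and adjusted p = 0.269 with an estimated correlation. This was also the 1 list that passed limma's fry, with an adjusted p of 0.0108.

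Erythroid markers fell by a median of 0.723 log2 units (limma camera adjusted p 1.69e-09; adjusted p = 0.320 with an estimated correlation). All 13 tested were lower, 8 at an unadjusted p under 0.05, and 6 passed when adjusted over the list alone against 0 over all genes. Ermap was 2.54-fold lower, Rhd 2.32-fold, the band 3 gene Slc4a1 2.01-fold and the transferrin receptor gene Tfrc 1.72-fold. The pair medians were uneven, at -0.945, -0.247 and -0.771 in pairs 1, 2 and 3. Without pair 2 the list's median was -0.961. The globin genes were not analysed here.

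Neutrophil and monocyte markers fell by a median of 0.598 log2 units (limma camera adjusted p 1.69e-09; adjusted p = 0.301 with an estimated correlation). Of 28 tested, 13 were lower and 0 higher at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Ly6g was 4.40-fold lower, Mmp8 3.50-fold and Retnlg 3.18-fold, whereas the precursor granule genes Mpo and Elane differed by 0.17 and 0.33 log2 units. The difference lay in pairs 1 and 2, with list medians of -0.94 and -0.90 against -0.11 in pair 3; pairs 1 and 2 are also those in which Xist differed. Without pair 2 the list's median was -0.41, and without pair 3 it was -0.90.

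T and NK cell markers fell by a median of 0.271 log2 units (limma camera adjusted p 6.58e-03; adjusted p = 0.301 with an estimated correlation), with members on both sides. Of 17 tested, 4 were lower and 3 higher at an unadjusted p under 0.05, and 2 lower and 1 higher passed when adjusted over the list alone, with 0 over all genes. The T cell receptor genes Cd3d and Cd3e were 2.78-fold and 2.51-fold lower. Thy1, also found on stem and progenitor cells, was 2.17-fold higher, the protease gene Gzmb 1.79-fold and Nkg7 1.39-fold. Other divisions of the 6 arrays gave up to 10 lists past camera's threshold.

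**Figure D2:**
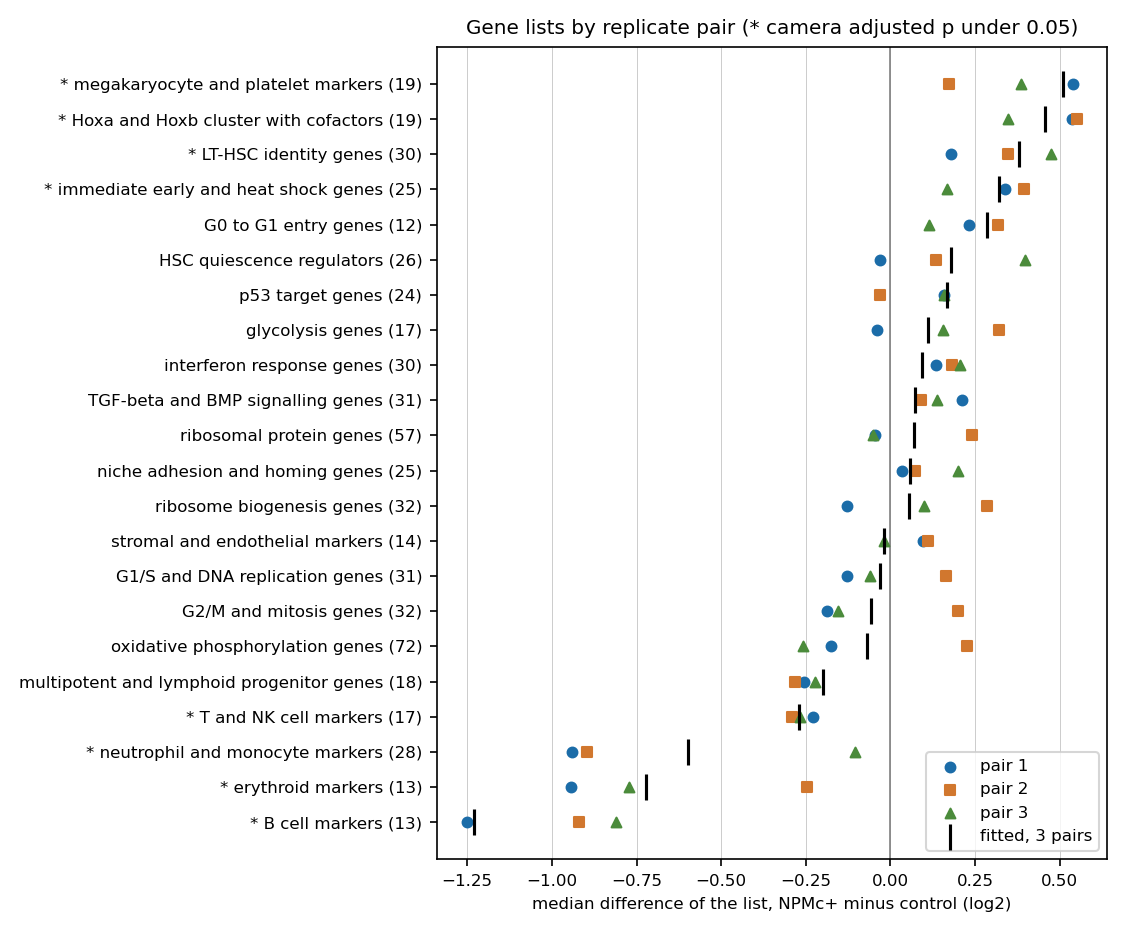
Median difference between NPMc+ and control in log2 units (x axis) for the 22 gene lists (y axis, with the number of genes tested); symbols are the medians in the 3 replicate pairs and black ticks the median of the fitted differences. Stars mark the 8 lists past camera's threshold, whose 3 pair medians lie on 1 side of 0, from B cell markers at -1.23 to megakaryocyte markers at 0.51.

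Genes of the cell cycle did not pass the test. Mki67, a marker of cycling cells, differed by -0.26 ± 0.17 log2 units (SE), and 0 of the 32 G2/M genes had an unadjusted p under 0.05 (median -0.06, limma camera adjusted p 0.364). For the 31 G1/S genes the median was -0.03 and the mean 0.01, with 1 higher and 1 lower at an unadjusted p under 0.05, and a limma camera adjusted p of 0.518. Pair 2 differed from the others: without it, the G1/S list (adjusted p 0.0157, median -0.16) and the G2/M list (0.0293, -0.11) were lower in limma's camera. With an estimated correlation and all pairs, adjusted p = 0.877 and 0.788. Of the inhibitors of cyclin-dependent kinases, Cdkn1a was 1.59-fold higher (0.67 ± 0.18, limma adjusted p 0.410), Cdkn1b differed by -0.04 ± 0.19 and Cdkn1c by -0.33 ± 0.21. In the list of entry from G0 into G1, 3 of 12 genes were higher at an unadjusted p under 0.05, Ccnd1 by 1.92-fold, E2f3 by 1.75-fold and Cdk6 by 1.53-fold; Myc was 1.31-fold higher (0.39 ± 0.19). The camera adjusted p of this list was 0.0691 in limma, with a median of 0.29. It was 0.0412 without pair 3, 0.0179 without the filter on dim genes and 0.0469 with an intensity trend, but 0.186 without pair 2, with a median of 0.17, and adjusted p = 0.320 with an estimated correlation.

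Of the 26 HSC quiescence regulators, 5 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The 5 were Mecom, Cdkn1a, Egr1, Nr4a1 and, at 1.44-fold, Cited2. Mecom is also an LT-HSC identity gene, Egr1 and Nr4a1 are also in the immediate early list, and Cdkn1a is also a p53 target. The quiescence list's median was 0.18 log2 units and its limma camera adjusted p 0.0863. The adjusted p was 0.0348 without pair 1 and 0.0179 without the filter on dim genes, but 0.765 without pair 3, where the median turned to -0.02, and adjusted p = 0.541 with an estimated correlation. Multipotent and lymphoid progenitor genes went both ways, with 3 of 18 higher and 5 lower at an unadjusted p under 0.05; 3 and 2 of these passed when adjusted over the list alone (limma camera adjusted p 0.0721). That list was past the threshold, in the lower direction, after quantile normalization (camera adjusted p 0.0347 in limma) and among genes above the 50th percentile (0.0359), but not with an estimated correlation (adjusted p = 0.320). The progenitor genes Cd27, Flt3 and Cd34 were 2.01-fold, 1.89-fold and 1.81-fold higher, while the lymphoid genes Ccr7 and Il7r were 3.12-fold and 2.39-fold lower.

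Among niche adhesion and homing genes, 3 of 25 were higher at an unadjusted p under 0.05, and 2 passed when adjusted over the list alone, the integrin gene Itga6 at 2.13-fold and Cd93 at 1.91-fold (limma camera adjusted p 0.364). In the TGF-beta and BMP list 5 of 31 were higher and 2 lower, and 1 of each passed when adjusted over the list alone: Smad5 was 1.73-fold higher and Id2 2.12-fold lower, and Smad3 was 1.93-fold higher (limma camera adjusted p 0.102, or 0.0452 without pair 2 and 0.0432 without the filter on dim genes; adjusted p = 0.320 with an estimated correlation). Of the 24 p53 targets, 4 were higher and 1 lower at an unadjusted p under 0.05, with 0 adjusted over the list alone; Xpc was 1.55-fold higher and Fas 2.02-fold lower (limma camera adjusted p 0.0863, or 0.0202 without pair 2 and 0.0319 without the filter; adjusted p = 0.320 with an estimated correlation). Interferon response genes had 4 of 30 higher, among them Igtp at 1.75-fold and Oasl2 at 1.61-fold, and a limma camera adjusted p of 0.365.

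Genes of metabolism and protein synthesis showed few differences. None of the 57 ribosomal protein genes and none of the 72 oxidative phosphorylation genes had an unadjusted p under 0.05 in limma, with camera adjusted p-values of 0.683 and 0.0515. The oxidative phosphorylation list had a median of -0.07 log2 units, with pair medians of -0.18, 0.23 and -0.26; without pair 2 its median was -0.19 and its limma camera adjusted p 1.45e-06. The list was also past the threshold, in the lower direction, without the block (camera adjusted p 0.0277 in limma), after quantile normalization (0.0173), among genes above the 50th percentile (0.00439) and with array weights (0.00624), but not with an estimated correlation (adjusted p = 0.788). Of 32 ribosome biogenesis genes 1 was higher at an unadjusted p under 0.05, Rrp12 at 1.43-fold (limma camera adjusted p 0.518). In glycolysis 2 of 17 were higher, Pfkl at 1.97-fold and the hexokinase gene Hk2 at 1.60-fold (limma camera adjusted p 0.0863, or 0.0236 without the filter on dim genes; adjusted p = 0.538 with an estimated correlation). Stromal and endothelial markers had 3 of 14 higher and 1 lower, with Pdgfrb 2.17-fold and Pecam1 1.69-fold higher and Emcn 1.71-fold lower; the median was -0.02, the mean 0.12, and the limma camera adjusted p 0.683 in the upward direction. None of the interferon, metabolism, protein synthesis, cell cycle and stromal genes passed when adjusted over its list alone.

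**Figure D3:**
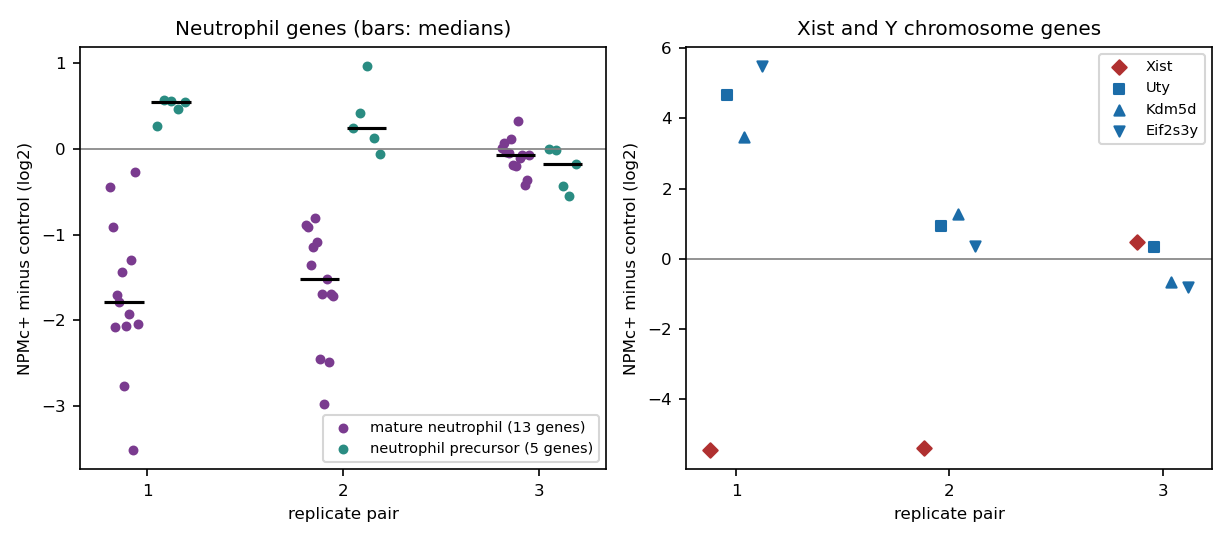
Difference between NPMc+ and control in log2 units (y axes) in each replicate pair (x axes). On the left, points are 13 genes of later neutrophil stages (labelled mature, though late precursors transcribe some) and 5 genes of early precursors. Bars mark the medians (-1.79, -1.52 and -0.07 for the later genes in pairs 1, 2 and 3). On the right, Xist lies at -5.44, -5.39 and 0.48 and the Y chromosome genes lie highest in pair 1.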

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

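The tests in this part were planned, and the choice of the blocked fit as the one reported was made after the data were seen. Without the block (no replicate block), genes past the threshold numbered 828 and genes at unadjusted p under 0.01 and 1.5-fold 726, against 0 and 388; gene lists past the threshold numbered 9, against 8. In the simulation, unchanged genes passed too often without the block, and fewer of the changed genes passed with it. Genes past the threshold numbered 3 at an adjusted p under 0.1 in limma (Ms4a1 and Ebf1 lower, and Mir5123 higher, named because they are so few) and 0 to 24 when a pair was left out. They numbered 0 under every other alternative run. Gene lists past the threshold numbered 13 without the filter on dim genes, 9 to 13 when a pair was left out, 0 with a correlation estimated for each list and 1 with fry. All 8 called lists were called in each of the 11 alternatives that change the fit, the values or the genes. With an estimated correlation the adjusted p was 0.301 for LT-HSC identity genes, Hoxa and Hoxb cluster with cofactors, megakaryocyte and platelet markers, neutrophil and monocyte markers and T and NK cell markers, 0.320 for immediate early and heat shock genes and erythroid markers, and 0.269 for B cell markers. With fry it was 0.106 for LT-HSC identity genes and megakaryocyte and platelet markers, 0.0788 for Hoxa and Hoxb cluster with cofactors and T and NK cell markers, 0.0867 for immediate early and heat shock genes, 0.207 for erythroid markers and 0.200 for neutrophil and monocyte markers. Both methods rest on the 2 residual degrees of freedom, and the test with an estimated correlation also uses them as its own. That test therefore has little power, and its failures do not show that a list was unchanged. The estimated correlation was below the preset 0.01 for the B cell (-0.0786), T and NK (-0.0567), Hoxa and Hoxb (-0.0248) and megakaryocyte (-0.0162) lists. For these, the loss of the call does not come from a higher correlation. For the other called lists it was 0.0427 to 0.551, highest for erythroid markers. Uncalled lists changed camera's direction: ribosome biogenesis genes (adjusted p 0.95) and ribosomal protein genes (0.677) did so among genes above the 50th percentile. Their medians stayed at 0.0559 and 0.0703 log2 units there. The median of all genes tested went from 0.032 to 0.086, so only the direction relative to the other genes turned. Without the filter on dim genes the median of all genes was -0.01. Other reversals came when a pair was left out. Over the 3 omissions the camera adjusted p ranged from 0.0157 to 0.923 for G1/S and DNA replication genes, 0.0293 to 0.958 for G2/M and mitosis genes, 0.102 to 0.465 for ribosome biogenesis genes, 0.262 to 0.49 for ribosomal protein genes and 1.45e-06 to 0.905 for oxidative phosphorylation genes, and the log2 fold change from -0.115 to 0.092 for Cdkn1b and from -0.0602 to 0.166 for Procr. The cause of the reversals on leaving out a pair was not tested. Oxidative phosphorylation genes were past the threshold in 5 settings: without the block, after quantile normalization, among genes above the 50th percentile, with array weights and without pair 2. In all, other settings moved 19 list results and 67 named gene results past their threshold in the same direction. Leaving out an array removes its pair, so the 6 planned omissions give 3 results. No background measurement was used, so dim genes are limited only by the filter.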

Other observations

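All gene groups in this and the next paragraph were chosen after the data were seen, 9 in all, and their adjusted p-values cover these 9 only. Gene families of mature immune cells fell in NPMc+ beyond the fixed lists in limma's camera test with a preset correlation. None passed with an estimated correlation (adjusted p = 0.265 to 0.290) or with fry (0.237 to 0.242), and their sizes were uneven between pairs. The 12 immunoglobulin kappa variable segments were all lower, 7 at an unadjusted p under 0.05, with a median of -1.33 log2 units (limma camera adjusted p 2.63e-08) and pair medians of -3.51, -0.68 and -0.97. Killer cell lectin-like receptor genes (Klr) fell by a median of 0.762, with 11 of 12 negative (7.03e-08; pair medians -0.22, -1.07 and -0.90), with Klrd1 3.77-fold and Klra2 3.54-fold lower. Stefin A genes, protease inhibitors of myeloid cells, fell by a median of 1.62, with 5 of 6 negative (1.95e-05; -2.25, -1.87 and -0.53). C-type lectin genes of the Clec4 family had a median of -0.47 (4.06e-05; -0.05, -0.77 and -0.49), with 7 of 9 negative and 2, Clec4a3 and Clec4a1, at an unadjusted p under 0.05. MHC class II genes fell by a median of 0.518, with 8 of 10 negative (2e-04; -0.31, -0.20 and -0.84): H2-Eb1 was 2.08-fold lower and H2-Aa 1.89-fold, while H2-DMa was 1.74-fold higher.

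Other groups lay near or above the threshold. Dendritic cell genes went both ways, with 4 of 11 positive, a median of -0.25 log2 units and pair medians of -0.34, -0.28 and -0.06 (limma camera adjusted p 0.0461; adjusted p = 0.274 with an estimated correlation). Siglech was 2.05-fold lower and Irf8 1.74-fold, while Flt3 was 1.89-fold higher. The 12 MHC class I genes had a median of 0.31, with H2-M3 2.23-fold higher (limma camera adjusted p 0.0461; adjusted p = 0.274 with an estimated correlation). That group first held 13 genes, with an adjusted p of 0.0555; H2-Ke6, which is not a class I gene, was then taken out, and so the side of the threshold rests on 1 member. Small nucleolar RNA genes went both ways, with 5 higher and 6 lower of 71 at an unadjusted p under 0.05 (limma camera adjusted p 0.068); this group first held 72 genes, with an adjusted p of 0.0576, until Snorc, not such a gene, was taken out. Eosinophil and mast cell genes had a median of 0.18 over 11 genes (0.621), with pair medians of 1.05, 0.34 and -0.76. The median of each of the 9 groups kept its sign under quantile normalization and median centring. Of the 16010 probe sets with no gene symbol, 0 passed the adjusted threshold in limma, and 289 had an unadjusted p under 0.01 where chance gives 160.

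The tests of mature cells, Hoxa genes and sex-linked genes in this part were chosen after the results were seen. So were 3 of the genes of later neutrophil stages (Ly6g, Mmp8 and Retnlg), while the counts of other splits were planned. The neutrophil test was widened from pairs 1 and 2 to all 3 pairs after its value was known, and the t tests over pairs were added last. The 6 arrays can be split in 10 ways, too few for a share under 0.05. The number of genes past the threshold was 0 in the real split and at most 0 in the others, so 10 of 10 splits were as large. Genes at an unadjusted p under 0.01 and 1.5-fold numbered 388, with a highest other count of 424, and 3 of 10 splits were as large. The other splits that call many genes leave pairs together and part only 1 pair. Such a fit takes its difference from that pair's own NPMc+ and control arrays, and each appears in 2 splits with the sign turned. These splits therefore carry the real contrast of 1 pair, and the shares of 10 are not shares of random divisions. Among the 4 splits that part all 3 pairs, the highest other count was 80. Lists past the threshold numbered 8, with a highest other count of 10, and 4 of 10 splits were as large, 2 of the 4 that part all pairs. For B cell markers the camera adjusted p was 5.62e-16 in the real split, and 0.0347, 0.0401 and 0.141 in the others that part all pairs.

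Lower markers of blood lineages may come from fewer cells of these lineages, mature or precursor, in the NPMc+ sorts or from less expression of these genes in the stem cells. The design gives no separate measure of purity. A single contaminating mixture, smaller in NPMc+, would move all its markers in 1 ratio in every pair. Between pairs 2 and 3 the 28 neutrophil and monocyte markers moved apart from the 13 erythroid markers by -1.65 log2 units. However, this contrast was picked from the pair medians and exists once, so it has no spread between pools. Megakaryocyte and platelet markers rose instead, with pair medians of 0.539, 0.172 and 0.385. Some of them, such as Itga2b, are also known from early progenitors, and whether they belong to such a mixture was not tested. Fewer neutrophils of later stages would lower later genes and spare genes of early precursors such as Mpo and Elane. The later genes include Ltf and Camp, granule genes that late precursors transcribe. The test therefore cannot tell mature neutrophils from late precursors. With genes averaged over the pairs, the medians differed by -1.13 over 13 and 5 genes. Within pairs 1, 2 and 3 they differed by -2.34, -1.77 and 0.11 (p 0.214 in a t test over the 3 pairs). The mixture and the neutrophil contrasts were first judged by permutation over genes (p 5e-05 and 0.0033), against the mixture and in favour of fewer neutrophils. Genes that vary together are not replicates, so after the values were seen neither was taken to decide. S100a8 and S100a9, 2 of the later genes, had control means of 12.65 and 12.10 log2 units. A mixture, fewer neutrophils, an effect of NPMc+ on the stem cells and the sources of the B cell and erythroid transcripts stay open.

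Higher Hoxa genes could reflect a larger share of stem cells in the NPMc+ sorts, in which case other stem cell genes would be higher by about as much. The 9 Hoxa genes were compared with the 27 LT-HSC identity genes outside the Hox and Meis families. With genes averaged over the pairs, the Hoxa median was higher by 0.646 log2 units (permutation over genes p 0.012). Within pairs 1, 2 and 3 it was higher by 0.706, 0.255 and 0.068 (p 0.212 in a t test over the 3 pairs). The t test covers these pair values, of which those of pairs 2 and 3 lie below 0.646. The comparison was first run with a bound of over 0.3 overall and above 0 in each pair, and its outcome was against the explanation. After these values were seen the bound was changed to over 0.3 in each pair, which changed the outcome to undecided. With an excess near 0 in pair 3, this comparison cannot tell a larger share of stem cells from an effect of NPMc+ on Hoxa genes. Other shifts in cell make-up were not tested. The progenitor genes Cd27, Flt3 and Cd34 were also higher, by 2.01-fold, 1.89-fold and 1.81-fold. Of the 18 multipotent and lymphoid progenitor genes, 3 were higher and 5 lower at an unadjusted p under 0.05 in limma. The 8 Hoxb genes had a median of 0.27 against 0.96 for Hoxa, a difference of 0.696 (permutation p 0.12).

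Sex-linked genes point to pools of unlike sex make-up, a source of difference that the labels do not mention. In pair 1, where the Y chromosome genes differed most, Xist differed by -5.44 log2 units while the Y genes differed by 4.55, which is consistent with more female cells in the control pool. Pair 2 had a Xist difference of -5.39 with only 0.86 for the Y genes, and pair 3 had 0.48 and -0.37. Whether sex contributes to the list results stays open, and no biological explanation of the sex-linked differences was tested.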
